A study of Homo sapiens with 5 samples.

How the data were processed

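RNA was measured in KGN cells, an established human granulosa tumour line, kept for 24 h in charcoal-stripped medium with 100 nmol/L androstenedione. The groups were a control, FSH at 100 ng/mL, forskolin (FSK), SC79 at 4 µg/mL and phorbol myristate acetate (PMA). The sample title calls the control untreated, while the written protocol has ethanol added to it. For FSK and PMA the sources differ on the unit. The treatment labels read 10 mmol/L FSK and 0.1 mmol/L PMA, while the written protocol has a symbol-font character before "mol" that stands for micro, which gives 10 µmol/L and 0.1 µmol/L. Each group has 1 library, made per the labels from 270 ng of total RNA pooled from 3 cultures of 3 different weeks, 90 ng from each. Poly(A) RNA was selected and turned into paired-end libraries with NEBNext Ultra kits, and strand specificity is not stated.

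The submitters' processing notes name Trimmomatic, kallisto and edgeR, without versions. The genome build and the transcript index are not given in the sources used here. Of 179973 Ensembl transcripts in the tables, 89.7% had an identifier and version found in GENCODE release 29 and 91.0% had the identifier alone, so coordinates are from that release on GRCh38. The tables carry 26 transcript biotypes, with 0 long noncoding RNA biotypes among them, and 303 transcripts have no gene name.

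The authors deposited estimated counts per transcript for each library, with "est_counts" in the column headings. They also deposited a normalized signal, which equals the estimated counts multiplied by 1 constant per library. These constants were 1.02 for control, 0.998 for FSH, 1.03 for FSK, 0.975 for SC79 and 0.934 for PMA, and the library totals were not equalised. A comparison table from the authors gives a log2 fold change per transcript for FSH, FSK, SC79, PMA and LH, each against control. The same deposited table gives a p-value and an adjusted p-value per transcript; its dispersion and its adjustment method are not given in the sources used here. All sample columns were matched to a group, with 0 left unmatched. The LH comparison has no library among the 5 used here.

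The following choices were made before the data were examined, unless said otherwise. Counts per gene had been planned, and because the tables are per transcript the estimated counts were summed over the transcripts of each of 35453 gene names. Library sizes were scaled with edgeR 4.0.16 (TMM) in R 4.3.3 on gene sums rounded to whole numbers. The control factor was 0.989 and the PMA factor 1.03. Log2 ratios used a pseudocount of 1 scaled count. A gene was counted as different when it lay at least 2-fold from control and had at least 100 scaled counts in the higher of the 2 libraries. With 1 library per group no p-value across genes was computed. Exact conditional binomial (Clopper-Pearson) 95% intervals of each ratio were taken from the rounded counts; they cover counting error only, since reads without molecular identifiers are not independent molecules. Where the control had 0 counts, the fold is given as a lower bound against 3 counts in that library. Neither the intervals nor this bound cover error in assigning reads between similar sequences. The other calculations ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.

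The 28 fixed gene lists covered steroidogenesis, cholesterol synthesis and uptake, cAMP-CREB targets, phorbol ester and AP-1 targets, ERK feedback and targets, NF-kB and cytokines, FOXO targets, EGF-like factors and cumulus expansion, granulosa identity and hormone receptors, cell division and DNA replication, angiogenic factors and receptors, extracellular matrix, TGF-beta and BMP targets, hypoxia and glycolysis, unfolded protein and amino acid stress, NRF2 and oxidative stress, metallothioneins, p53 targets, interferon response, apoptosis regulators, fatty acid synthesis, components of the PKA, PKB and PKC pathways, markers of theca and stroma, immune cells, endothelium, epithelium and oocytes, and reference genes. Members needed a mean of at least 20 scaled counts over the 5 libraries. For the 24 lists with at least 5 such members, the median log2 ratio was ranked among 10000 random lists of the same size matched in 10 bins of mean expression. A percentile under 2.5 or above 97.5 is called outside the random range. Of 96 list and treatment pairs, 45 were outside, where 4.8 are expected for lists of randomly drawn genes. Genes of a fixed list can move together between any cultures, and all treatments share the control library. The 4.8 is therefore not the number expected between untreated cultures, and the excess is not a measure of treatment effect.

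The genes named for each treatment were the 8 highest and 8 lowest ratios among genes with a symbol past the 2-fold rule, and the 2 largest and 2 smallest ratios of each list described, among members with at least 100 scaled counts in the higher library. FSHR, STAR, CYP11A1, CYP19A1, HSD3B2, NR4A1, FOSL1, DUSP6 and TXNIP were fixed for every treatment. Some genes that this rule selects are not reported. Genes named outside this rule are said to be chosen after their values were seen.

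The FSH profile was set beside those of FSK, SC79 and PMA by correlation and covariance across 14584 genes. Reference values came from 100 simulated sets of unchanged libraries with a shared control, with counting noise alone or with an added spread of 0.0709 log2 units per library taken from the closest pair, FSH and control. Shared 2-fold genes were set beside the number that independent draws would share.

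The calculations were tested on simulated data built from these libraries. In each simulated comparison 50 of 50 genes planted at 3-fold and 50 of 50 at 8-fold passed the size rule, and 0 of 50 planted at 1.5-fold did. Of 12229 unchanged genes in the FSH simulation, 0 passed, and 95.5% of intervals held the true ratio. These simulations carry counting noise only, so they do not say how many genes would pass between repeat cultures.

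The alternatives tried were DESeq2 1.42.0 size factors, total counts, the authors' normalized values, minimums of 20 and 4 or of 500 and 100 counts, no minimum, a pseudocount of 5, the mean of the other treated libraries as reference, single transcripts, protein-coding genes only, 20 expression bins, list means, Spearman correlation and contrasts that share no library. A count over genes with at least 80% of their 31-base words found in no other gene of the tables was added after the data were seen. So was the overlap of 2-fold genes as given in the text, which takes each treatment's own genes, because a minimum in both comparisons drops genes by their count in the other treatment. The histone genes with mostly their own sequence were taken apart after the data were seen, too. The authors' normalized values shift the median log2 ratio over all genes by -0.16 for FSH, -0.16 for FSK, -0.28 for SC79 and -0.24 for PMA, because depth stays in them. The shifts of the DESeq2 and total count scalings were at most 0.06. Sample-level tests, replicate spreads and batch checks were left out because each group has a single pooled library.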

Results

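KGN is an established human cell line from a granulosa cell tumour, and granulosa cells are the cells of the ovarian follicle that bind follicle-stimulating hormone (FSH) and make oestradiol. Polyadenylated RNA was sequenced after 24 h in 5 groups with 1 library each. These were a control given ethanol per the protocol, FSH, forskolin (FSK, which activates adenylate cyclase and through cAMP protein kinase A, PKA), SC79 (an activator of AKT, also called PKB) and phorbol myristate acetate (PMA, an activator of protein kinase C, PKC). The series is about the signalling pathways that gonadotropins use in granulosa cells. Library totals, in units of 1e+06 estimated counts, were 58.8 for control, 53.5 for FSH, 52.3 for FSK, 50.3 for SC79 and 52.2 for PMA. The 10 most abundant genes held 6.66% of the counts in the PMA library and up to 8.76% in the SC79 library. Each library pooled 3 cultures, so there is no replicate error and no difference reported here has a replicate check. Values are scaled estimated counts per gene and log2 ratios to control, and bracketed ranges are exact 95% intervals that cover counting error only.

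The comparison of FSH with control asks which transcripts differ after the hormone itself. STAR, which carries cholesterol into mitochondria for steroid synthesis, and CYP19A1, the aromatase that makes oestrogens, were both higher with FSH. Genes that answer to cAMP, such as NR4A3 and PDE4B, were also higher, and genes of cell division were slightly lower. Most other genes lay close to control. Of 12471 genes compared, 93.7% lay within 1.2-fold of control, 38 were at least 2-fold higher and 13 at least 2-fold lower. Many of these share sequence with other genes. Among genes with mostly their own sequence, 25 were higher and 2 lower.

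STAR (ENSG00000147465, chromosome 8, 38143649 to 38151265 on GRCh38) had 1011 scaled counts in control and 3531 with FSH, a 3.49-fold difference [3.26 to 3.74]. CYP19A1 (ENSG00000137869, chromosome 15, 51208057 to 51338610) had 900.5 and 2564, or 2.85-fold [2.65 to 3.07]. CYP11A1 (ENSG00000140459, chromosome 15, 74337759 to 74367740), which cleaves the cholesterol side chain, had a log2 ratio of 0.53. HSD3B2, which makes progesterone, had a log2 ratio of 1.63 from 12.8 counts in control, with an interval of 1.75 to 6.47-fold. The receptor gene FSHR (ENSG00000170820, chromosome 2, 48962157 to 49154537) was low, with 92.6 counts in control and 111 with FSH, and its interval of 0.905 to 1.58-fold includes no difference. NR5A2, a nuclear receptor that drives steroidogenic genes, was lower at -0.30, and STARD4, a cholesterol carrier, at -0.12. The 18 measured steroidogenesis genes had a median of 0.03, inside the random range at percentile 91.6.

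Highest among FSH genes with their own sequence were KIF26A, an atypical kinesin, at a log2 ratio of 3.43 and GALNT15, which starts O-linked glycosylation, at 2.66. CTNNA2, an alpha-catenin of cell adhesion, followed at 2.33 and VWA5B2, a von Willebrand factor domain protein, at 2.25. IGFBP4, an IGF-binding protein chosen after its values were seen, was 1.84 higher. The other genes of the 8 highest were ITGB1P1, H3F3AP4 and SRP9P1, which are processed pseudogenes, and SMIM11B, a small membrane protein gene. ITGB1P1 had 0 counts in control and 810.0 with FSH, at least 294-fold higher, while H3F3AP4 had 2.25 and 415, a ratio with an interval of 62.3 to 1876-fold. With FSK, ITGB1P1 had 0.41 counts, and its share of own 31-base words is not known. Neither range covers reads assigned to the wrong one of similar sequences, so these folds may not be real differences. SRP9P1 had a log2 ratio of 2.53 and SMIM11B of 2.48, and H3F3AP4 and SRP9P1 have 0% own 31-base words and SMIM11B 8.89%. The 8 lowest genes were of the same kind for the larger part. SMN1, the spinal muscular atrophy gene, was at -2.12 with 10.4% own words, EIF3CL, a translation factor copy, at -1.56 with 1.52%, and SMIM11A at -1.46 with 6.85%. NUDT4P1 and FAM60DP, both pseudogenes or copies, were at -1.22 and -1.18, and the pseudogene NPM1P40 had 354.7 counts in control and 154.1 with FSH. PLA2G4B, a phospholipase, was at -1.09 with 26.5% own words. LPAR4, a lysophosphatidic acid receptor, was at -1.03 with 99.7% own words. Besides LPAR4, the clone-named gene AL356432.3, chosen after its values were seen, was lower with FSH among genes with mostly their own sequence, with 9621 counts in control and 150.7 with FSH. Its share of own words, 80.1%, lies just past the minimum of 80%. It had 8694 counts with FSK, 8123 with SC79 and 4336 with PMA, and reads assigned to similar sequences are not excluded.

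Among cAMP-CREB targets 21 of 27 genes were above 0 with FSH and the median log2 ratio was 0.23, above all matched random lists at percentile 100. NR4A3, an orphan nuclear receptor, was at 1.31 and PDE4B, a cAMP phosphodiesterase, at 1.19, while CREM, a cAMP-responsive transcription factor, was at -0.14 and CITED2 at -0.08. NR4A1, the related receptor, was at 0.27. Hypoxia and glycolysis genes had a median of 0.10 (percentile 100) with 18 of 20 above 0, with CA9, a carbonic anhydrase, with 188.6 counts in control and 433.1 with FSH, and NDRG1, a stress-response gene, at 0.22, with PFKP and SLC2A1 lowest at -0.10 and -0.04. The ERK feedback list was at 0.04 (percentile 98.8), with SPRY1 at 0.34 and SPRY4 at 0.18, both inhibitors of growth factor signalling, and EPHA2 at -0.15 and CCND1 at -0.12. With the mean over members this list was inside the random range. Genes of cell division had a median of -0.22 (percentile 0) and 27 of 28 were below 0. The mitotic kinases PLK1 and CDK1 were at -0.43 and -0.40, and the replication genes MCM7 and MCM3 at 0.00 and -0.01. The 4 treatments share the control library, and between SC79 and FSH the cell division median was 0.03, inside the random range. An unusual control library and a similar lowering by both treatments are not separated by these values. FOSL1, an AP-1 subunit, DUSP6, an ERK phosphatase, and TXNIP, a glucose-responsive gene, were at -0.08, -0.09 and -0.01. The remaining lists were inside the random range for FSH. Cholesterol synthesis was at 0.03, with TM7SF2 at 0.33, granulosa identity at 0.02, with the AMH receptor gene AMHR2 at 0.50, and extracellular matrix at -0.04, with the proteoglycan gene BGN at -0.57. Phorbol ester targets were at 0.02, NF-kB genes at 0.00, FOXO targets at 0.02, EGF-like genes at -0.01, angiogenic factors at -0.03 and TGF-beta targets at -0.01. Unfolded protein genes were at 0.00, NRF2 targets at -0.03, p53 targets at -0.04, interferon genes at 0.05, apoptosis regulators at 0.01 and fatty acid synthesis at 0.01. Pathway components were at 0.00, theca and stroma markers at -0.03 and epithelial markers at 0.01.

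The comparison of FSK with control shows what direct activation of the cAMP pathway does in the same cells. CYP19A1, CYP11A1 and STAR, 3 genes of steroid synthesis, were far higher with FSK. The cAMP targets PDE3A and STC1 were higher too, and so was INHA, the inhibin alpha subunit that granulosa cells secrete. The 28 measured genes of cell division and DNA replication, with AURKB and MKI67 among them, were each at least 2-fold lower. Of 12606 genes, 521 were at least 2-fold higher and 683 at least 2-fold lower, with 154 and 182 at 4-fold, and 52.5% lay within 1.2-fold of control.

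CYP19A1 had 27409 scaled counts with FSK against 900.5 in control, a 30.4-fold difference [28.6 to 32.5]. CYP11A1 had 12434 against 825.3, or 15.1-fold [14.1 to 16.1], and STAR 10078 against 1011, or 9.96-fold [9.37 to 10.6]. HSD3B2 was 5.36-fold higher from 12.8 counts, with a lower interval limit of 3.18-fold. The steroidogenesis median was 0.54 (percentile 100), with NR5A2 at -0.83 and STARD4 at -0.68 the lowest members. FSHR was at 0.50, with an interval of 1.09 to 1.87-fold.

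The 8 highest genes with FSK began with LGALS12, a galectin, with 1.83 counts in control and 379.2 with FSK, a ratio between 56.8 and 1714-fold. GALNT15 followed at a log2 ratio of 6.13, KIF26A at 6.02 and HTRA3, a secreted serine protease, at 5.91. PDE3A, a cAMP phosphodiesterase, was at 5.90, IL18R1, an interleukin receptor chain, at 5.79, and PTGES, which makes prostaglandin E, at 5.55. SPINK4, a protease inhibitor, had 1.83 counts in control and 144.2 with FSK, between 21.4 and 656-fold. Lowest of the 8 lowest was MYBL2, a cell cycle transcription factor, which had 3939 counts in control and 276.8 with FSK, a log2 ratio of -3.83. ZNF367 (a zinc finger factor) was at -3.53, PKMYT1, a kinase that holds CDK1 inactive, at -3.45, and the replication factor MCM10 at -3.40. AURKB (a mitotic kinase) was at -3.35, OLFML2B, a matrix protein, at -3.30, TCF19 at -3.21 and UHRF1, which maintains DNA methylation, at -3.19.

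Of the 28 cell division genes all 28 were at least 2-fold lower with FSK, with a median of -2.18 (percentile 0). MKI67, the proliferation marker, was at -3.16, and the smallest differences were PCNA at -1.06 and MCM7 at -1.18. Among cAMP-CREB targets the median was 1.53 (percentile 100), with 17 of 27 at least 2-fold higher. STC1, a secreted glycoprotein, was at 4.50 and NR4A1 at 1.34, while FOSB and GEM, early-response genes, were lower, FOSB at -1.35 and GEM with 1366 counts in control and 595.5 with FSK. Granulosa identity genes had a median of 0.30 (percentile 99.6), with CYP19A1 at 4.93 and INHA at 3.88, and with KITLG, the ligand of KIT on the oocyte, at -1.73 and NR2F2 at -0.53. EGF-like and cumulus expansion genes were at 0.28 (percentile 99.5) and went both ways, with AREG, an EGF receptor ligand, at 2.57 against HAS2, which makes hyaluronan, at -2.61 and PTX3, a matrix protein of the cumulus, at -1.73.

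Further lists outside the random range with FSK had smaller medians. Hypoxia and glycolysis genes were at 0.35, with CA9 at 1.64 and ANKRD37 at 0.87 against PFKFB3 at -0.94. NRF2 targets were at 0.32, with the cystine carrier SLC7A11 at 1.68 and AKR1B10, an aldo-keto reductase, at 1.36, against HMOX1 at -0.71. TGF-beta and BMP targets were at 0.25, with ID2 at 2.20, GREM1 at 1.49 and TGFB2 at -1.02. Unfolded protein and amino acid stress genes were at 0.22, with DNAJB9 at 1.12 and PSAT1 and ASNS, which make serine and asparagine, at -2.07 and -1.55. Extracellular matrix was at -0.22, with FBN1 (fibrillin) at 0.82 and TNC (tenascin) at -1.53. p53 targets were at -0.32, with GDF15 at 0.61 and the cell death gene PMAIP1 at -1.66. Cholesterol synthesis was at -0.17, with TM7SF2 at 1.34 and ACAT2 at -0.69. Epithelial markers were at -0.46, KRT19 being lowest at -1.89, but inside the random range with lower minimums. With the mean over members the NRF2 and TGF-beta lists were inside that range, and so were cholesterol synthesis at 0.00210 and unfolded protein genes at -0.0272, whose signs turned. The phorbol ester and AP-1 list was inside the range at 0.16, where TFPI2 and IL11 were at 4.55 and 4.32 while PLAT and FOSL1 were at -2.34 and -2.25. Also inside were theca and stroma markers at -0.34, apoptosis regulators at 0.11, where BCL2L11 was at 1.74 and BCL2 at -2.72, and interferon genes at -0.13. ERK feedback genes were at 0.03, NF-kB genes at -0.03, FOXO targets at 0.05 with KLF9, a zinc finger factor, at 3.30, angiogenic factors at -0.20 with ANGPT1 at 2.23, fatty acid synthesis at -0.08 and pathway components at -0.12. DUSP6 was at -0.56 and TXNIP at -0.42.

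The comparison of SC79 with control concerns the AKT pathway. NQO1, a quinone reductase, and other targets of the oxidative stress factor NRF2 were higher with SC79, and interferon-stimulated genes such as IFI6 were higher as well. The genes MT1F, MT1X, MT2A and MT1E of metallothioneins, which bind metal ions, were lower by less than 2-fold. Of 12482 genes, 28 were at least 2-fold higher and 5 lower, and 90.7% lay within 1.2-fold. Among genes with mostly their own sequence, 4 were higher, among them IFI6, NQO1 and PIR, and 2 were lower, NPTX1 and ESM1, where PIR was chosen after its values were seen.

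NQO1 had 8657 counts in control and 22923 with SC79, a 2.65-fold difference [2.58 to 2.71], and IFI6, an interferon-induced mitochondrial protein, had 847.3 and 2342, or 2.76-fold [2.56 to 2.99]. HSPA6, a strictly inducible heat shock protein, had 1.83 and 128.8, a ratio between 19.1 and 588-fold, with 43.3% own 31-base words. ITGB1P1 had 0 counts in control and 1055 with SC79, at least 384-fold higher if reads were assigned correctly, a limit that holds for FSH too. The read-through genes C1QTNF3-AMACR and ABHD14A-ACY1 were at 1.91 and 1.53, GOLGA8G, one of a family of golgin copies, at 1.51, and SULT1A4, a sulfotransferase with a near-identical copy, at 1.38, each with under 15% own words. PLA2G4B was lowest among genes with a symbol at -1.62, then NPTX1, a neuronal pentraxin, at -1.16 and ESM1, an endothelial proteoglycan, at -1.08. The other 2 lower genes, AC022384.1 at -1.29 and AC233968.1 at -1.96, were chosen after their values were seen and have at most 2.77% own words.

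Of 16 NRF2 targets 15 were above 0 with SC79 and the median was 0.57 (percentile 100). AKR1B10 was at 1.23, and the smallest ratios among abundant members were those of GCLM, of glutathione synthesis, at 0.12 and HMOX1, haem oxygenase, at 0.18 with an interval of 0.985 to 1.31-fold. Of 19 interferon genes 18 were above 0, with a median of 0.41 (percentile 100). OAS1, an antiviral synthetase, was at 0.92, while DDX58, an RNA sensor, was at -0.08. The metallothioneins MT1F, MT1X, MT2A and MT1E were at -0.67, -0.55, -0.48 and -0.39. FOXO targets, which AKT represses, were inside the random range at 0.01 (percentile 73.5), with PIK3IP1 at 0.19 and TXNIP at -0.22. CYP19A1 was at 0.62, or 1.53-fold [1.41 to 1.67], AKR1C3, which reduces androstenedione, at 0.66 and STAR at 0.40, and the steroidogenesis median was 0.09 (percentile 99.4) with NR5A2 at -0.56. CYP11A1 was at 0.23, HSD3B2 at 0.52 with an interval of 0.697 to 3.22-fold, and FSHR at -0.34 with one of 0.572 to 1.08-fold.

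Several signalling lists were slightly lower with SC79. The EGF-like list was at -0.18, with HBEGF, an EGF receptor ligand, at -0.82 and PTX3 at -0.48. NF-kB genes were at -0.14, where 17 of 20 lay at or below 0 and the cytokine IL32 was at -0.53. Hypoxia genes were at -0.13, with CA9 at -0.49 and the mitophagy gene BNIP3 at -0.43, and phorbol ester targets were at -0.12. Cell division genes were at -0.19 with 27 of 28 below 0, where CCNE2 (cyclin E2) was at -0.70 and CDC6 at -0.49 and AURKB at 0.05. Epithelial markers were at -0.15. p53 targets were at 0.10, TGF-beta targets at 0.06 and unfolded protein genes at 0.06, with TP53I3, ID2 and SLC7A11 highest at 0.39, 0.29 and 0.93. With the mean over members the epithelial and steroidogenesis lists were inside the random range, and so were phorbol ester targets at 0.0165, whose sign turned. Inside the random range were the cAMP-CREB list at -0.05, cholesterol synthesis at 0.00, ERK feedback at -0.01, granulosa identity at 0.00, angiogenic factors at 0.01, extracellular matrix at -0.07, apoptosis regulators at -0.02, fatty acid synthesis at -0.01, pathway components at -0.06 and theca and stroma markers at 0.00. NR4A1, FOSL1 and DUSP6 were at 0.07, -0.13 and -0.12.

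The comparison of PMA with control asks which transcripts differ after 24 h with a PKC activator. These data do not show whether PKC was still active at that time. Matrix metalloproteinases that degrade collagen, MMP1, MMP9 and MMP10, had few or 0 counts in control and were abundant with PMA. The plasminogen system genes SERPINB2 and PLAT and the cytokines IL24, IL1B and CXCL8 were higher as well. COL3A1, a collagen, and SPARC were lower, and so were the smooth muscle genes TAGLN and ACTA2. Of 28 genes of cell division and DNA replication, 16 were at least 2-fold lower. Of 12645 genes, 460 were at least 2-fold higher and 458 lower, with 146 and 53 at 4-fold, and 55.2% lay within 1.2-fold.

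MMP1, interstitial collagenase, had 16.5 counts in control and 10302 with PMA, a log2 ratio of 9.20, and MMP9, gelatinase B, had 3.67 and 5117, or 10.10. MMP10, stromelysin 2, had 0 counts in control and 656.4 with PMA, at least 239-fold higher. SERPINB2, an inhibitor of plasminogen activators, had 56.9 and 11458 (7.63), and IL24, a cytokine of the interleukin 10 family, was at 7.11. CSRP3, a muscle LIM protein, had 0 and 136.4, at least 49.6-fold higher. The pseudogenes ITGB1P1 (0 and 709.2, at least 258-fold) and H3F3AP4 (2.25 and 332.8, between 49.9 and 1506-fold) completed the 8 highest. Their ranges do not cover reads assigned to the wrong one of similar sequences. Among the lowest were SFRP5, a Wnt antagonist, at -4.03, FAM46B, a poly(A) polymerase, at -3.93, and ZNF423, a BMP-responsive zinc finger factor, at -3.48. DCAF8L2 was at -3.39, NTNG1 (netrin G1) at -3.14, TDGF1, a Nodal co-receptor, at -2.98, and ALDH1A3, which makes retinoic acid, at -2.94 with 11600 counts in control and 1508 with PMA.

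Phorbol ester and AP-1 targets ranked at percentile 100, with 21 of 24 above 0 and 14 at least 2-fold higher, while FOSL1 and GDF15 were lower at -1.07 and -0.55. NF-kB genes had a median of 0.70 (percentile 100), with IL1B at 2.58 and CXCL8, a neutrophil chemokine, at 2.53 against CXCL1 at -0.49. ERK feedback genes were at 0.30, where the phosphatases DUSP5 and DUSP6 were at 2.01 and 1.26 and DUSP4 at -0.96, with EPHA4 at 1.42 and EPHA2 at -0.87. The cAMP-CREB list was at 0.54 (percentile 100), led by STC1 at 6.18 and RGS2, a brake on G protein signalling, at 2.86, with CREB5 at -0.47 and NR4A1 at 0.56. Angiogenic factors were at 0.44, with ANGPTL4 at 3.02 and VEGFA at 1.81 and the vasoconstrictor EDN1 at -1.68. PTGS2, the inducible prostaglandin synthase, was at 2.93 and AREG at 2.58 in an EGF-like list with a median of 0.25, where PTGER4 was at -1.25. FOXO targets were at 0.32, FBXO32 being highest at 1.40 and SESN3 lowest at -1.77. With the mean over members FOXO targets, angiogenic factors and fatty acid synthesis were inside the random range, and so was the EGF-like list with higher minimums.

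Steroidogenic genes were split with PMA. STAR was 5.32-fold higher [4.99 to 5.68] and CYP19A1 1.87-fold higher [1.73 to 2.03]. CYP11A1 was at -0.30, and AKR1C2 and AKR1C1, which reduce steroids, were lower at -1.87 and -1.55, and the list median was -0.20 (percentile 2.08). That list was inside the random range with lower minimums (-0.17), with no minimum (-0.0908) and with the mean over members (-0.0119). HSD3B2, at 0.20, had an interval of 0.520 to 2.58-fold. FSHR was lower at -1.32, with 36.6 counts against 92.6 [0.263 to 0.581-fold], and FOXL2, the transcription factor of granulosa identity, was at -0.87. INHBA, the activin subunit, was at 1.11, and the granulosa list was inside the random range at -0.13. Cholesterol synthesis was at -0.31, with FDPS at 0.25 and NSDHL at 0.22 its highest members and 4 of 24 above 0, and fatty acid synthesis at -0.29, with FADS2 at -0.79.

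Extracellular matrix genes had a median of -0.74 (percentile 0) with PMA. COL3A1, collagen III, was at -1.93 and SPARC at -1.68, with 283330 counts in control and 88276 with PMA, while FBN1 was at 0.53 and BGN at 0.56. Cell division genes had a median of -1.11 (percentile 0). BUB1, of the spindle checkpoint, was at -1.84 and CCNB2 (cyclin B2) at -1.76, while the helicase genes MCM5 and MCM7 were higher at 0.31 and 0.21. NRF2 targets were at -0.34, with NQO1 at -1.17 and TXNRD1 at 0.42, and p53 targets at -0.40, with BTG2 at -1.38 and ZMAT3 at -1.37. Hypoxia genes were at 0.20, with CA9 at 1.91 and NDRG1 at 1.29. MT2A was at 1.35 but MT1F at -1.48. Theca and stroma markers had a median of 0.49 with 4 of 7 above 0, but a mean of -0.40, so the direction turned with the summary used, and PDGFRA and RGS5 were at 0.70 and 0.78 and TAGLN and ACTA2 at -2.33 and -2.29. The endothelial marker genes TIE1, PECAM1 and VWF were at 3.27, 2.57 and 1.26, and CD68, a lysosomal gene used as a macrophage marker, was at 1.46. TXNIP was at 0.33. Inside the random range for PMA were TGF-beta targets at 0.11, with GREM1 at 2.35, interferon genes at -0.01, apoptosis regulators at 0.11, pathway components at -0.03, where PRKAR2B was at -1.47, unfolded protein genes at -0.05 and epithelial markers at -0.10.

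The reference genes were inside the random range with each treatment, at medians of 0.02 for FSH, 0.09 for FSK, 0.00 for SC79 and 0.04 for PMA. Even so, ACTB (beta-actin) was at -0.59 with FSK and the ribosomal protein gene RPLP0 at -0.67 with PMA. Of the oocyte markers ZP3 alone passed the minimum, with 16.7 counts in control and 33.3 with FSH. Among immune markers PTPRC and CD68 passed it.

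**Figure D1:**
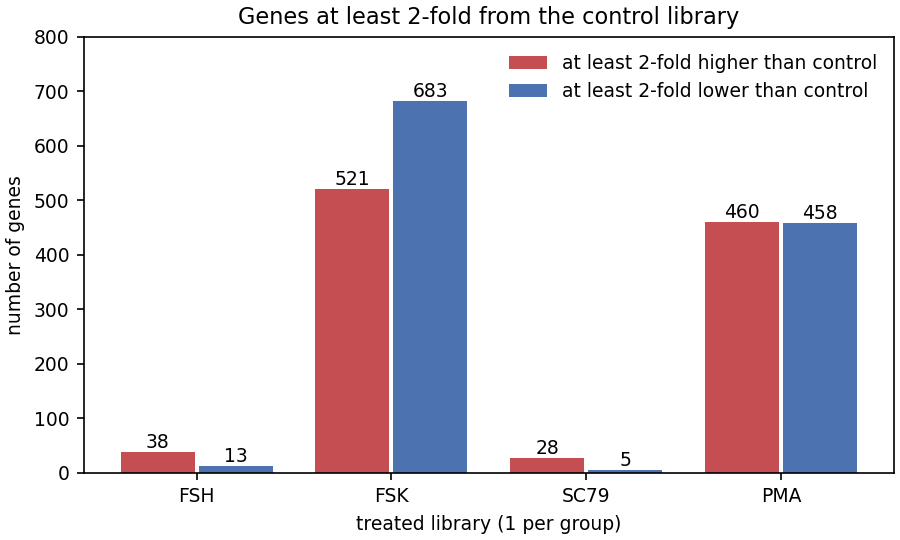
Number of genes at least 2-fold higher (red) or lower (blue) than control in each treated library, 1 library per group, among genes with at least 100 scaled counts. FSK gave 521 and 683 genes and PMA 460 and 458, against 38 and 13 for FSH and 28 and 5 for SC79.

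**Figure D2:**
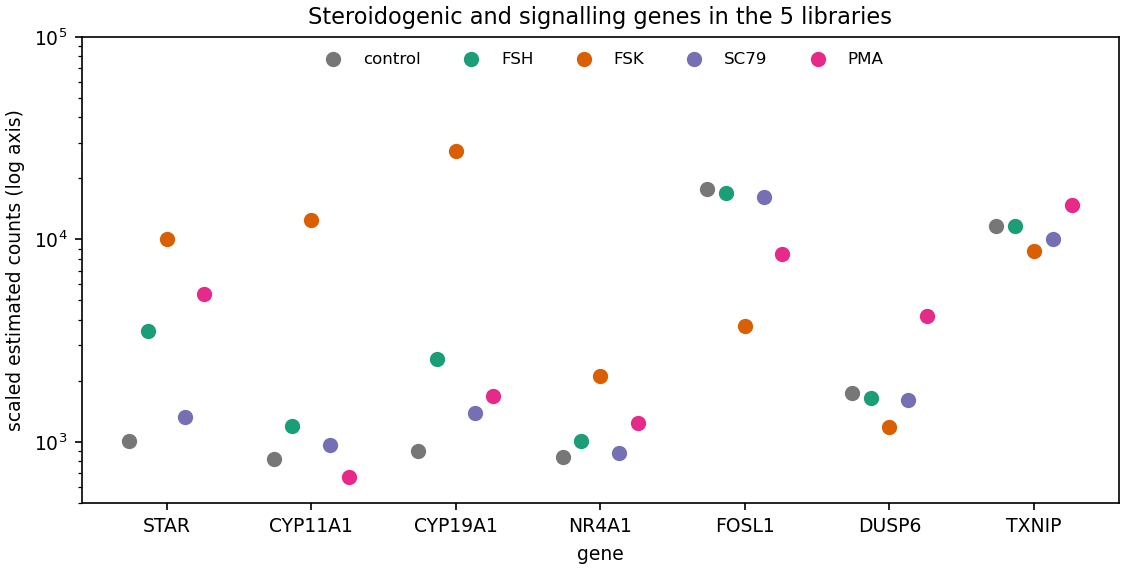
Scaled estimated counts (log axis) of 7 genes in the 5 libraries, 1 point per library. CYP19A1 was highest with FSK at 27409, and STAR was higher with FSH at 3531, PMA at 5377 and FSK at 10078 than in control at 1011.

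**Figure D3:**
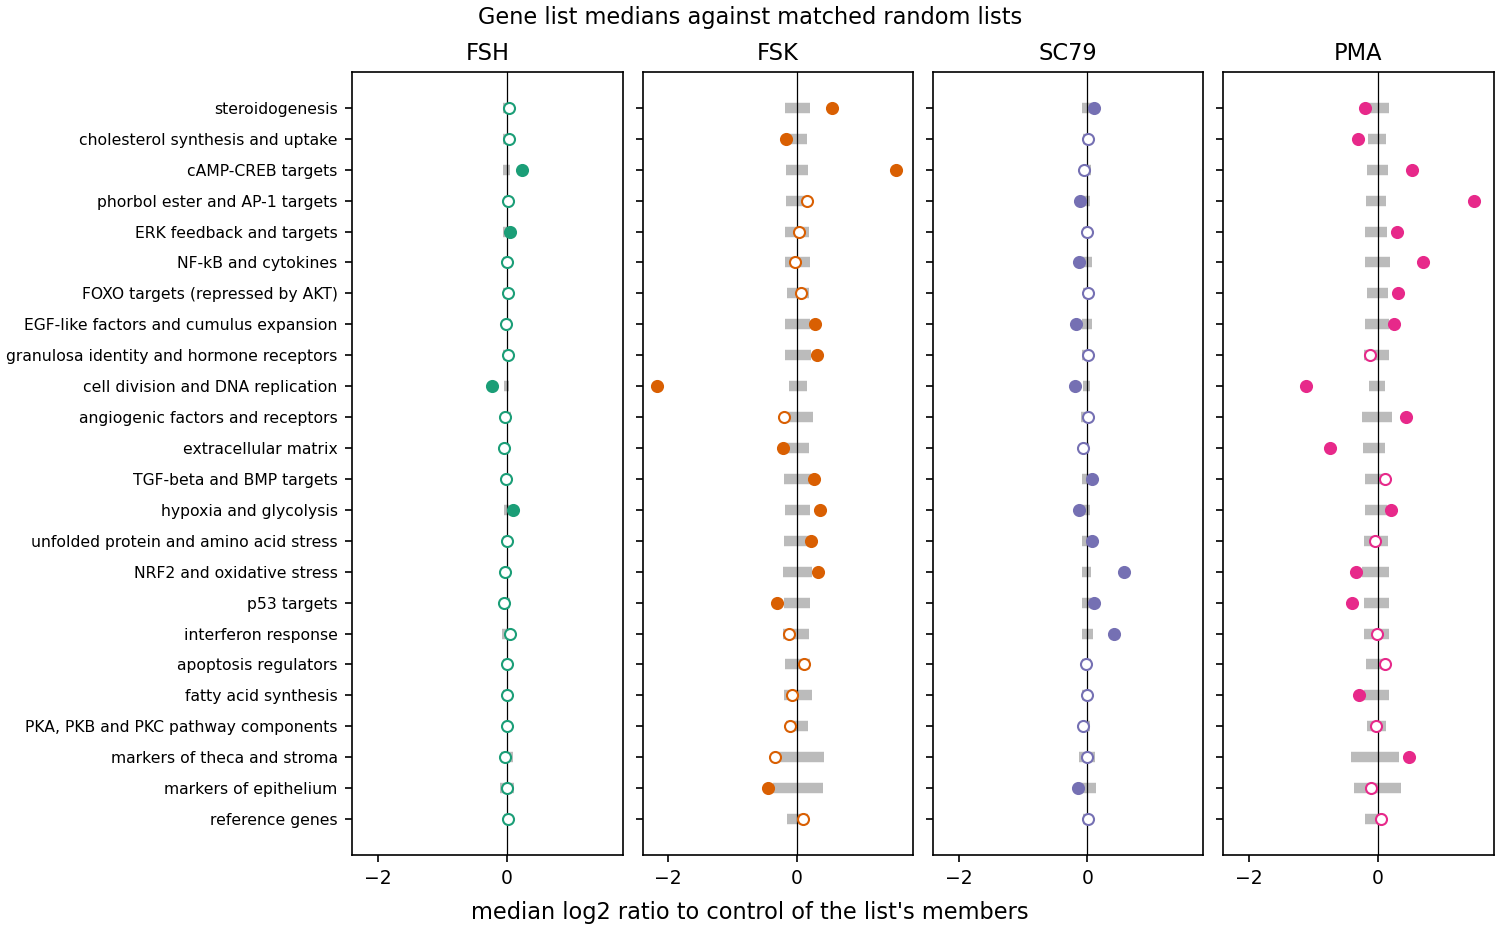
Median log2 ratio to control of 24 gene lists in each treated library, with grey bars for the central 95% of matched random lists and filled points outside them. Cell division genes were at -2.18 for FSK and -1.11 for PMA, and phorbol ester targets were above the bar for PMA.

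The likeness of the FSH profile to each activator bears on which pathway FSH uses. Of the genes at least 2-fold higher with FSH, most were also higher with FSK. Among them were STAR, CYP19A1, PDE4B, NR4A3, KIF26A and GALNT15. Of the 38 genes at least 2-fold higher with FSH, 31 were among the 521 that were so with FSK. Independent draws would share 1.56. Simulated unchanged libraries with a shared control shared 0, counted with the minimum in both comparisons. That 0 carries no weight, because unchanged genes did not pass the 2-fold rule in the simulated data. Neither number covers an unusual control library, which both comparisons would share. Among the shared genes with mostly their own sequence, the SC79 ratio was highest for GALNT15, at 0.72 against 2.66 with FSH. A control library low in these genes would raise the SC79 ratios as much as those of FSH. For these genes the values argue against an unusual control as the single source, though an effect of SC79 on them would enter too. CYP19A1 was at 1.51 with FSH and 4.93 with FSK, and KIF26A at 3.43 and 6.02. With PMA the overlap was 17 of the 38 against 1.38 for independent draws, and with SC79 it was 7 of the 38 against 0.0848. The simulations gave 0 for each, with the same limit, and hold no error in assigning reads. Several of these shared genes are pseudogenes such as ITGB1P1. All 7 shared with SC79 have at most 10.7% own 31-base words or, for ITGB1P1, an unknown share. Reads assigned to the wrong one of similar sequences could therefore give the whole SC79 overlap. The genes shared with PMA also include STAR, NR4A3 and PDE4B, which have at least 87.2% own words. Of the 13 genes lower with FSH, 2 were also lower with FSK. These were SMIM11A at -1.44 and the pseudogene HMGB1P5, with 608.1 counts in control and 302.7 with FSK, the latter chosen after its values were seen. SMIM11A fell from 329.4 counts in control to 119.3 with FSH and 121.1 with FSK, while SMIM11B rose from 51.7 to 292.5 and 250.7. With 6.85% and 8.89% own 31-base words, reads moving between similar sequences could give both. HMGB1P5 has 22.0% own words. LPAR4 was lower with FSH but higher with FSK, with 118.4 counts in control, 57.4 with FSH and 238.3 with FSK.

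Across 14584 genes, which are not independent replicates, the log2 ratios of FSH had a Pearson correlation of 0.431 with those of FSK, 0.497 with SC79 and 0.335 with PMA. The Spearman values were 0.480, 0.416 and 0.321. All ratios share the control library, and simulated unchanged libraries gave 0.481 for FSK, 0.479 for SC79 and 0.487 for PMA. In those libraries the ratios vary by noise alone, so the shared control gives such correlations by construction. The observed correlations therefore cannot be weighed against them by size. The covariances were larger than simulated: 0.0951 for FSK, 0.0455 for SC79 and 0.0700 for PMA, against 0.0143, 0.0143 and 0.0144. An unusual control library would raise the covariances too. In contrasts that share no library, FSH over control was set against each activator over the mean of the other activators. The correlation was then 0.180 with FSK, -0.219 with SC79 and -0.00145 with PMA. The SC79 and PMA values have FSK in their reference, so a likeness of FSH to FSK lowers them. They do not show that FSH and SC79 act in opposite ways.

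The activators were also compared with each other, since the design separates the pathways. FSK and PMA went opposite ways for PLAT and for a gene of antigen presentation. The genes named here were chosen after their values were seen. PLAT, tissue plasminogen activator, was at -2.34 with FSK and 3.26 with PMA. DUSP5 was at -1.09 and 2.01, and VEGFC, a lymphatic growth factor, at -1.04 and 1.14. In the other direction SLC7A11 was at 1.68 with FSK and -1.16 with PMA. Also, NPY (neuropeptide Y) was at 3.72 and -2.03, CRISPLD2, a secreted glycoprotein, at 2.28 and -2.57, and HLA-DRA, an antigen-presenting chain, at 2.44 and -1.24. Of the genes past the 2-fold rule, 121 were higher with both and 185 lower with both, against 18.7 and 24.5 for independent draws, while 27 were higher with FSK and lower with PMA and 30 the reverse, against 18.7 and 24.6. All these ratios use the same control library.

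Directly between FSK and PMA, phorbol ester targets were lower with FSK by a median log2 ratio of -1.32, NF-kB genes by -0.70 and cell division genes by -1.17. Granulosa identity genes were at 0.79, cAMP-CREB targets at 0.77, extracellular matrix at 0.54 and steroidogenesis at 0.33, all higher with FSK. Between PMA and SC79 the phorbol ester list was at 1.69 and NRF2 targets at -0.97. Between FSK and SC79 the cAMP-CREB list was at 1.65, cell division at -1.97 and interferon genes at -0.60. The numbers of 2-fold genes were 737 higher and 651 lower for PMA over FSK, 566 and 500 for SC79 over FSK, 468 and 411 for PMA over SC79, and 24 and 41 for SC79 over FSH.

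The authors' deposited table compares single transcripts. Per that table, CYP19A1 and CYP11A1 passed an adjusted p of 0.05 with FSK, with a log2 fold change of 4.88 (adjusted p 0.00905) for the most abundant CYP19A1 transcript and 4.00 (0.0386) for that of CYP11A1. STAR did not, at 3.37 with FSK (0.107) and 1.82 with FSH (0.908). In edgeR comparisons from the authors, 3239 transcripts passed for FSH, 3955 for FSK, 3317 for SC79 and 3900 for PMA. The smallest absolute log2 fold change among them was 3.97 for FSH, 3.88 for FSK, 3.99 for SC79 and 3.93 for PMA. Summed per gene, the total lay within 1.5-fold of control for 97.3% of the FSH transcripts, 97.4% of the SC79 transcripts, 73.2% of the FSK transcripts and 77.8% of the PMA transcripts. Rounded counts were 0 in 1 of the 2 libraries for 93.3% (FSK) to 94.6% (SC79) of them.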

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

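The tests in this part were chosen after the result was seen, except the count of LHCGR sequence words shared with other genes. The authors' deposited table holds a comparison of LH with control, whose library was not used here, so these values rest on that table alone and the difference was not tested. In it the most abundant transcript of LHCGR, the LH receptor gene, has a log2 fold change of 14.0 (adjusted p 9.77e-07), and 4 of 6 LHCGR transcripts pass the authors' threshold. In the 5 libraries used here LHCGR had 2.12 to 13.5 scaled counts. The 19 measured interferon genes have a median log2 fold change of 5.84 in the LH comparison, with all 19 above 0. The highest of 7 OAS2 transcripts is at 14.0, of 11 OAS1 transcripts at 13.2 and of 32 IRF7 transcripts at 11.1. The transcripts of these genes most abundant in the 5 libraries are lower, at 5.96, 7.59 and 5.84. In that comparison 4926 transcripts pass the authors' threshold, against 3239 for FSH. Of those for FSH with a gene name, 94.3% had rounded counts of 0 in 1 of the 2 libraries, and for LH this share is not known. STAR is at 0.01 there and CYP19A1 at -0.73. Other lists stand out there too. The cAMP-CREB list is at 0.51 with 18 of 26 above 0, phorbol ester targets at 1.07, NRF2 targets at 0.91 and NF-kB genes at 0.63, each at percentile 100. Extracellular matrix is at -0.84 and cell division at -0.55, both at percentile 0.01.

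No explanation of the LH values was settled. That the antiviral genes rank high as a list, at percentile 100, restates the values above and decides nothing on an interferon response in those cells. LH acting through cAMP was left open for LHCGR, because its most abundant transcript is at 6.26 (adjusted p 0.144) in the authors' FSK comparison while the other LHCGR transcripts there range from -4.48 to 5.24, and the counts of this gene are too few to decide. The cAMP-CREB list does not decide it either, since it ranks at percentile 100 in the authors' PMA comparison as well. Shared reads were left open too, with 83.9% of the 31-base words of LHCGR found in no other gene. Cells made to carry extra LHCGR were not tested either.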

How the results depend on the processing

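The tests here were chosen before the data were examined, apart from the count over genes with mostly their own 31-base words. No paired analysis was possible because each group has 1 pooled library. Of 45 list results outside the random range, 45 stayed outside on the same side of it under DESeq2 factors, total counts, the authors' normalized values, a pseudocount of 5 and 20 expression bins. The sign of the median was not compared there. The downward shift of all genes under the authors' normalized values can turn small positive medians negative. Where a value below moved, the cause was not tested unless stated.

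With the authors' normalized values, SC79 had 16 genes higher (28 in the main analysis) and 17 lower (5), and PMA had 739 lower (458). With genes of mostly their own 31-base words, FSH had 25 higher and 2 lower, and SC79 had 4 and 2. With protein-coding genes only, FSH had 7 lower. Minimums of 20 and 4 counts gave 136 higher and 76 lower for FSH, 119 and 71 for SC79 and 720 and 693 for PMA, and minimums of 500 and 100 gave 12 and 4, 6 and 1, and 278 and 294. With no minimum the numbers were 1222 and 1104 for FSH, 2723 and 2018 for FSK, 2072 and 1072 for SC79, and 2095 and 1769 for PMA. Single transcripts gave 1072 and 885 for FSH, 2244 and 2472 for FSK, 1194 and 918 for SC79, and 2241 and 1903 for PMA.

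List medians moved inside the random range in these cases. With the mean over members, ERK feedback was at 0.0299 for FSH. For FSK, NRF2 was at 0.32, TGF-beta at 0.0919, cholesterol synthesis at 0.00210 and unfolded protein genes at -0.0272. For SC79, epithelium was at -0.12, phorbol ester targets at 0.0165 and steroidogenesis at 0.10. For PMA, FOXO was at 0.11, angiogenic factors at 0.33, fatty acid synthesis at -0.26, theca and stroma at -0.40 and steroidogenesis at -0.0119. The sign turned for cholesterol synthesis and unfolded protein genes with FSK, phorbol ester targets with SC79, and theca and stroma with PMA. With minimums of 20 and 4, epithelium was at -0.27 for FSK and -0.13 for SC79, and steroidogenesis at -0.17 for PMA. With minimums of 500 and 100, EGF-like genes were at 0.15 for PMA. With no minimum, cholesterol synthesis was at -0.0521 and epithelium at -0.0870 for FSK, epithelium at -0.15 for SC79 and steroidogenesis at -0.0908 for PMA.

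In contrasts that share no library, each activator was set over the mean of the other activators. They gave correlations of FSH of 0.180 with FSK, -0.00145 with PMA and -0.219 with SC79. With the other treated libraries as reference they were -0.424 with FSK and -0.468 with PMA. That reference contains the FSK and PMA libraries, so by construction a gene higher with them falls below it. FSH then had 130 genes higher and 73 lower, and SC79 150 and 165. For FSH, cAMP-CREB was at -0.40, cell division at 0.95, ERK feedback at -0.11 and hypoxia at 0.00547, with CYP19A1 at -0.64, NR4A3 at -0.53, GALNT15 at -0.35, STAR at -0.24 and PDE4B at -0.18. For SC79, cell division was at 1.05, TGF-beta at 0.0788, epithelium at 0.0754, steroidogenesis at 0.0333 and unfolded protein genes at -0.0131. For FSK, NRF2 was at 0.18, extracellular matrix at 0.13, cholesterol synthesis at -0.0335 and p53 targets at -0.0939. For PMA, FOXO was at 0.0502, theca and stroma at 0.0768, cAMP-CREB at -0.0698 and cell division at -0.0293. The sign also turned there for extracellular matrix with FSK, epithelium and unfolded protein genes with SC79, and cAMP-CREB with PMA.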

Other observations

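The tests in this part were chosen after the result was seen, except the contrast that shares no library and the NRF2 members with mostly their own sequence. Genes of MHC class II, which present antigens to T cells, were higher with FSK and for the larger part lower with PMA, in a group chosen after its values were seen. The median log2 ratio of 11 genes was 2.32 with FSK, 0.44 with FSH, -0.01 with SC79 and -0.63 with PMA. With PMA 10 of the 11 were below 0, and HLA-DRA and HLA-DMA passed the 2-fold rule. CIITA, the regulator of these genes, had 581.1 scaled counts in control, 2376 with FSK and 557.8 with PMA, and HLA-DRA had 1852 in control, 10066 with FSK and 784.9 with PMA. HLA-DMB was at 3.17 with FSK and HLA-DQA1 at 0.79, the latter at 0.05 with PMA. Under the authors' normalized values the group medians were 2.15 for FSK, 0.29 for FSH and -0.86 for PMA.

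Genes of replication-dependent histones and of ribosomal proteins were also chosen after their values were seen. Histone genes had a median of 1.26 with FSK and 1.07 with PMA, with HIST1H2AC at 1.76 and HIST1H1C at 1.90 in the respective treatment. These values cover polyadenylated RNA only. Histone RNA without a poly(A) tail was not measured, so they do not give the total RNA of these genes. Several share sequence, HIST2H3A and HIST2H3C having the same counts and 0% own 31-base words, and the 15 with mostly their own words had medians of 1.25 and 1.10. HIST1H4C was lower with FSK, at -1.28 from 29.3 counts. Ribosomal protein genes had a median of -0.53 with PMA, with 79 of 83 below 0, and of -0.13 with FSK, with 77 of 83 below 0.

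Of the 38 genes at least 2-fold higher with FSH, 31 were so with FSK, with NR4A3, CYP19A1 and STAR among them. The correlation over all genes, 0.431, cannot be weighed against the 0.481 of simulated unchanged libraries, whose ratios vary by noise alone. The covariance was 0.0951, against 0.0143 simulated, though an unusual control library would raise it too. A weaker cAMP signal was left open, because the cAMP-CREB list ranked at percentile 100 with FSH but also with PMA, where STAR was at 2.41, NR4A3 at 1.42 and CYP19A1 at 0.91. The control library that both share was left open over all genes, at a correlation of 0.180 for contrasts that share no library, but ruled out for 230 genes at least 4-fold higher with FSK than with PMA. Their FSH over SC79 median of 0.28, without control, ranked at percentile 100, though an effect of SC79 on them would enter it. Carried-over FSK RNA was ruled out as the single source, since the share it would need lay over 2 SD from the median share for 42.0% of 81 genes.

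NRF2 and interferon lists were higher with SC79. An odd control library was ruled out, as SC79 over FSH ranked at percentile 100 for both lists, with medians of 0.63 and 0.34. Reads shared between similar genes were ruled out for NRF2, whose 12 members with mostly their own sequence had a median of 0.38 at percentile 100. Lasting AKT activity, which would lower FOXO targets such as TXNIP, was left open at percentile 73.5. An effect of SC79 apart from AKT could also give this, and these data hold no test of it.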
